A study of Mus musculus with 8 samples.

How the data were processed

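Chromatin immunoprecipitation sequencing measured ASXL1 in wild-type cells, and the histone marks H3K4me2, H3K4me3 and H3K27me3 in wild-type and Asxl1-/- cells. The cells were mesenchymal stem and progenitor cells grown from mouse bone marrow, of the C57BL/6 background, at passages 5 to 10 per the labels. Of the 8 samples, 7 have a peak list, and the input library was not analysed here because it has none. Each combination of target and genotype is 1 library, so there are no replicates.

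Reads were aligned with BWA and islands, here called peaks, were called with SICER 1.1 on mm10, per the submitters' processing notes. The version of BWA, the calling parameters, the control and the false discovery limit are not given in the sources used here. The deposited lists give the chromosome, the start and the end of each peak, a running number and a library name. They hold no read count, score, fold enrichment or p-value, so the depth of each library is unknown. All starts and ends lie on multiples of 200 bp. The smallest gap between neighbouring peaks was 400 bp in the H3K4me2 and H3K4me3 lists and 800 bp in the ASXL1 and H3K27me3 lists. Lists were made per library, and the lists of a mark share the same grid and smallest gap in both genotypes. Without counts, a peak present in 1 genotype and missing from the other may differ little in signal, and a weaker or shallower library gives fewer or narrower peaks.

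Peaks were compared as intervals, with 1 bp as the least overlap, on the 19 autosomes and the X chromosome. Counts of overlapping peaks were checked with bedtools 2.31.1 and were equal. Gene positions came from a RefSeq gene table of GRCm38.p6, which has the same coordinates as mm10. That table gives gene starts and ends but no strand, exon or transcript, so exons, introns and untranslated regions could not be assigned. The plan was to use transcription starts. Instead, a gene counted as marked when a peak lay within 1000 bp of either end of the gene, and the text calls these places gene ends. There were 21631 protein-coding genes, of which 7048 have an end of another protein-coding gene within 2000 bp of an end of their own. A mark was called kept at a gene when both genotypes had a peak there, lost when wild type alone had it, and gained when Asxl1-/- alone had it. Of the kept genes, 20 for H3K4me2, 17 for H3K4me3 and 36 for H3K27me3 had the mark at different ends in the genotypes. A width given for a gene is that of the whole peak that reaches its end, and the part of it that the other genotype also covered was computed.

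The planned ranking of peaks by a statistic of the peak caller could not be made, since the lists give none. Peak width took its place after the lists had been seen. Named genes follow a rule written before the data were examined, apart from that replacement. Per mark it takes the 8 lost and the 8 gained genes with the widest peak. For ASXL1 it takes the 10 genes with the widest peak and the 8 widest among those that lost H3K4me3. It takes up to 4 changed genes of each of 18 gene lists, and Asxl1 itself, and passes over genes named only by a clone or a prediction. All 385 genes of the lists were found in the gene table. Some genes that the rule takes are not reported here, while counts and random lists keep every gene. Where changed members of a list are counted, all of them may be named, beyond the rule, and other genes named outside it are said to be so where they appear. The planned ratio of read density at shared peaks was not computed.

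Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only. No test between genotypes was made, because 1 library per group leaves no estimate of the spread. Overlap of ASXL1 with the marks was set beside 1000 sets of random regions of the same widths on the same chromosomes. Changes in a gene list were set beside 10000 random lists of the same size, matched for losses on wild-type peak width in 5 classes. For Hox genes, runs of neighbouring genes as long as the clusters were also drawn. Genes with ASXL1 were set beside genes without it in the same width classes. These percentiles describe these libraries and are not p-values for a genotype effect. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated lists in which 200 of the 21631 genes lost a mark, the procedure recovered 200 for each of the 3 marks, with 0 false gains. The simulated lists were the wild-type lists with all peaks at those genes removed. This outcome was therefore fixed, and it checks the code but not errors of peak calling. Of 400 random lists, 5% fell in the top 5% of their random draws, and of 400 lists with a planted excess 99.5% did. The planted lists were longer than the gene lists used here, so 99.5% does not measure the power for those. Alternatives covered the overlap rule, the window, the gene set, the peak set and its length, the chromosomes and the matching.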

Results

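The study mapped where the chromatin regulator ASXL1 sits in wild-type mesenchymal stem and progenitor cells of mouse bone marrow, and how 3 histone marks differ in cells without Asxl1. H3K4me3 marks active or poised promoters, H3K4me2 marks promoters and enhancers, and H3K27me3 is the mark that Polycomb repressive complex 2 places on silent genes. There was 1 library of each kind, so no difference below has a replicate check, and each describes these libraries. Wild type gave 17419 ASXL1 peaks over 107.7 Mb, with a median width of 4600 bp. H3K4me2 gave 36048 peaks in wild type and 33589 in Asxl1-/-, H3K4me3 gave 17884 and 15276, and H3K27me3 gave 17712 and 20249. The covered length was 138.9 Mb in wild type and 129.0 Mb in Asxl1-/- for H3K4me2, 68.4 and 72.4 Mb for H3K4me3, and 214.5 and 232.9 Mb for H3K27me3. The files hold no read counts, so the depth of the libraries is unknown.

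At Asxl1 itself, on chromosome 2 from 153345830 to 153404007 in mm10, H3K4me2 and H3K4me3 peaks were present in both genotypes. The H3K4me3 peak was 7.2 kb wide in wild type and 6.2 kb in Asxl1-/-. Wild type had an ASXL1 peak of 9.0 kb there. The ASXL1, H3K4me2 and H3K4me3 peaks lay at the gene end near 153345830. Asxl1-/- alone had an H3K27me3 peak, of 23.2 kb, and it lay at the opposite end, near 153404007. These peaks do not check the genotype, because the lists do not show which part of the gene was deleted, and no ASXL1 library of Asxl1-/- cells is among the samples.

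Most H3K4 methylation was at the same places in both genotypes, and H3K27me3 overlapped less. H3K4me3 peaks of Asxl1-/- cells overlapped a wild-type peak in 91.5% of cases (95% interval 91.1 to 91.9), and 79.8% (79.2 to 80.4) of wild-type peaks overlapped 1 of Asxl1-/-. For H3K4me2 the shares were 78.4% (78.0 to 78.9) and 72.7% (72.3 to 73.2). For H3K27me3 they were 59.8% (59.1 to 60.5) and 64.3% (63.6 to 65.0). Unshared peaks were narrower: wild-type H3K4me3 peaks had a median width of 1600 bp when unshared and 3800 bp when shared. H3K4me3 was in fewer but wider peaks in Asxl1-/-, and among 13154 peaks paired 1 to 1 the median width ratio of Asxl1-/- over wild type was 1.1, with 59.8% wider in Asxl1-/-. The ratio was 0.966 for H3K4me2 and 0.980 for H3K27me3.

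Whole chromosomes differed between the genotypes, in a like order for all 3 marks. On chromosome 3 the length covered in Asxl1-/- was 0.532 of wild type for H3K4me2, 0.70 for H3K4me3 and 0.222 for H3K27me3. On chromosome 10 the ratios were 1.35, 1.45 and 2.09. Chromosome 13 was low in all 3 marks, at log2 ratios of -0.70, -0.34 and -1.03, and chromosome 14 was high, at 0.31, 0.34 and 1.03. Chromosome 4 was split, since up to 120 Mb its ratios were 0.590, 0.775 and 0.324, and beyond it they were 1.06, 1.16 and 1.18. Because of this structure, counts of genes that changed an H3K4 mark are also given for the autosomes on which the log2 ratio of the other H3K4 mark lay within 0.2 of its autosomal median. On the 10 autosomes chosen so for H3K4me3, Asxl1-/- covered 0.893 of the wild-type length in H3K4me2 and 1.02 in H3K4me3, and on the 11 chosen for H3K4me2 it covered 1.01 in H3K4me3 and 0.880 in H3K4me2.

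**Figure D1:**
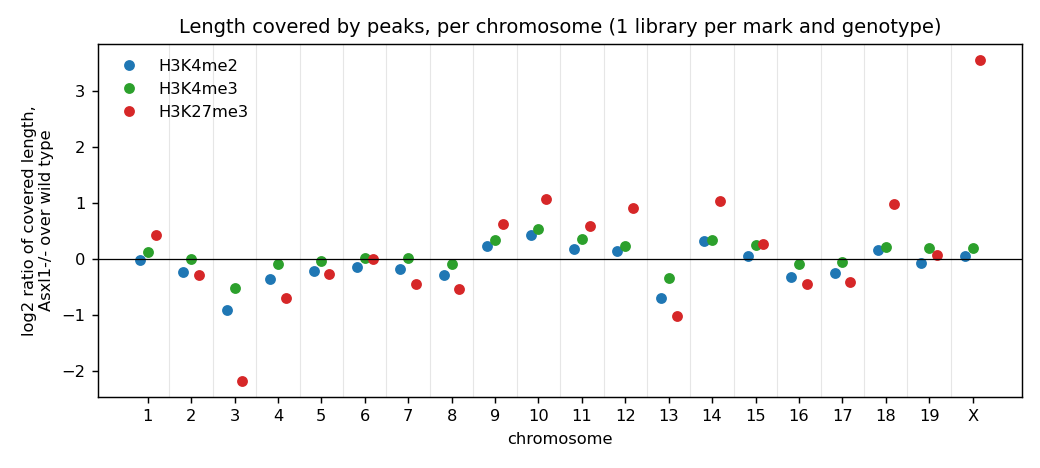
Log2 ratio of the length covered by peaks in Asxl1-/- over wild type (vertical axis) for each chromosome (horizontal axis), with 1 point per mark. The 3 marks rank the autosomes alike, from -0.91 for H3K4me2 on chromosome 3 to 0.43 on chromosome 10, and H3K27me3 on the X chromosome stands at 3.54.

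H3K4me3 differed between the genotypes at a small share of genes, with Meox2 at the head of the losses. H3K4me3 was kept at 12214 genes, lost at 536, which is 4.20% (3.86 to 4.57) of those marked in wild type, and gained at 484. With peak lists cut to equal length by width, 324 lost it and 872 gained it, so which change was more frequent is not settled. On the 10 autosomes near the median 312 genes lost it and 233 gained it. Of the genes that lost it, 92.2% (89.6 to 94.3) had a wild-type peak that overlapped no peak of Asxl1-/-, and of those that gained it 68.0% (63.6 to 72.1) had an Asxl1-/- peak that overlapped none of wild type. At the others the other genotype had part of the peak, but not at the gene end. The widest lost peak was at Meox2, a homeobox regulator of mesoderm, with 10.6 kb in wild type. Meox2 also lost an H3K4me2 peak of 13.8 kb. Whole peaks were also lost at the collagen gene Col11a1 (8.6 kb), Cd34 (8.4 kb), a surface marker of progenitors, Ankrd1 (8.2 kb), a target of YAP, and Ecm1 (8.0 kb). At Bri3 (10.2 kb), the interleukin 11 receptor gene Il11ra1 (8.8 kb) and Gipc1 (8.0 kb), 9.2, 3.6 and 5.2 kb of the peak stayed covered in Asxl1-/-. Cd34 kept H3K4me2, in a peak of 9.8 kb in wild type and 1.6 kb in Asxl1-/-. Il11ra1 lies on chromosome 4, and Col11a1 and Ecm1 on chromosome 3, where covered length was lower in Asxl1-/- for all 3 marks. Bri3, Il11ra1, Ecm1 and Gipc1 have an end of another protein-coding gene within 2000 bp of the marked end, so the peak may belong to that neighbour.

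The widest peak at a gene that gained H3K4me3 lay over Hoxc8, with 43.4 kb in Asxl1-/-, of which 34.4 kb was also covered in wild type. It was followed by the peaks at Kcnk7 (26.8 kb), the glutamate receptor gene Grin3b (25.8 kb), Proca1 (21.8 kb), Ptprcap (20.2 kb), Fam178b (19 kb), the histone deacetylase gene Hdac7 (18.2 kb) and Ubtf (18.2 kb), which codes for an activator of ribosomal RNA genes. Wild type covered from 50.5 to 81.2% of each of these 8 peaks, so these were peaks that reached further in Asxl1-/-. Kcnk7, Grin3b, Proca1, Ptprcap, Fam178b and Hdac7 also have another gene end within 2000 bp of the marked end. Lost peaks had a median width of 1700 bp in wild type and kept ones 4600 bp, so most losses were of narrow peaks.

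H3K4me2 was kept at 13356 genes, lost at 415 (3.01%, 2.73 to 3.31) and gained at 649. In the wider 50% of each list 1095 lost it and 950 gained it, so which change was more frequent is not settled. On the 11 autosomes near the median 272 genes lost it and 335 gained it. Of the genes that lost it 77.3% (73.0 to 81.3), and of those that gained it 84.1% (81.1 to 86.9), had a peak that overlapped none of the other genotype. The widest wild-type peaks at genes that lost it included those at Spaca4 (22.4 kb), Egfl8 (15.6 kb), Rcc1l (15.6 kb), Il34 (14.6 kb), a ligand of the macrophage colony stimulating factor receptor, and Zfp787 (14.6 kb). Of the 8 widest, 7 were over 50% covered in Asxl1-/-, and Meox2 was the 1 that lost the whole peak. The widest Asxl1-/- peaks at genes that gained it were at Hoxc4 (65.4 kb, with 54.4 kb also covered in wild type), the adaptor gene Sorbs3 (31.8 kb), Csrp1 (31.6 kb), Cend1 (17.4 kb), Slurp1 (16.6 kb), Fscn2 (16.4 kb), Creb3l3 (16.0 kb) and the costimulatory ligand gene Cd80 (14.6 kb). Of these 8, 5 were over 50% covered in wild type, Slurp1 was 45.8% and Creb3l3 40.0% covered, and Cd80 gained the whole peak. Egfl8, Hoxc4, Cend1, Fscn2 and Creb3l3 have another gene end within 2000 bp of the marked end. Hoxc4, Slurp1 and Cd80 gained H3K4me3 as well, with 5.2, 7.6 and 10.8 kb. Of the genes that lost H3K4me2, 106 also lost H3K4me3, and of those that gained it 149 also gained H3K4me3.

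H3K27me3 changed at a larger share of genes than the other marks. It was kept at 4305 genes, lost at 1474, which is 25.5% (24.4 to 26.7) of those marked in wild type, and gained at 1097. Of the gains 257 were on the X chromosome. On autosomes 1464 genes lost the mark and 840 gained it. On the 10 autosomes chosen by H3K4me2 the counts were 885 and 362, but H3K27me3 itself covered 0.911 of its wild-type length there, from 0.687 to 1.34 by chromosome. Over all annotated genes 2872 lost it and 2852 gained it. Of the genes that lost it 73.2% (70.9 to 75.4), and of those that gained it 78.6% (76.0 to 81.0), had a peak that overlapped none of the other genotype. The widest wild-type domains at genes that lost it were at Col20a1 (179.2 kb), Uvssa (141.0 kb), Aldh1b1 (128.2 kb), Ppie (113.0 kb), Arv1 (91.4 kb), Eif3d (89.2 kb), Acacb (87.2 kb), which codes for an acetyl-CoA carboxylase, and Capn10 (75.4 kb). Asxl1-/- still covered from 55.7 to 95.5% of each of these 8 domains, with 84.6 kb at Ppie, so the mark went from a gene end and not from the whole domain. Of these, Uvssa, Aldh1b1, Ppie, Arv1, Eif3d and Capn10 had H3K4me3 in both genotypes. The widest Asxl1-/- domains at genes that gained it were at Card10 (198.6 kb), the ephrin gene Efnb1 on the X chromosome (115.6 kb), Ackr3 (112.4 kb), a scavenging receptor for CXCL12, Loxhd1 (94.8 kb), Clmn (94.4 kb), Enthd1 (73.4 kb), Sfi1 (73.0 kb) and Glce (72.4 kb). Wild type covered over 50% of 5 of these 8, 33.9% at Clmn, 5.71% at Efnb1 and none at Sfi1. Such a wide domain reaches several genes, and these are the genes at whose ends it began or stopped being called.

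Genes with H3K4me3 and H3K27me3 at the same end, a combination known from poised developmental genes, fell from 2618 in wild type to 2145 in Asxl1-/-. On autosomes alone they fell from 2566 to 2007. The shifts of whole chromosomes enter these counts and were not removed. On chromosome 3, 159 genes lost H3K27me3 and 1 gained it, while on chromosome 10, 30 lost it and 96 gained it. Of the 2618, 1533 had both at the same end in Asxl1-/-, which is 58.6% (56.6 to 60.5), and 55 had both at different ends, which is 2.10% (1.59 to 2.73). A further 719 had H3K4me3 alone, which is 27.5% (25.8 to 29.2), and 274 had H3K27me3 alone, which is 10.5% (9.32 to 11.7). Other genes entered the combination in Asxl1-/-. Of these, 340 had H3K4me3 alone in wild type, 209 H3K27me3 alone, 40 both marks at different ends and 23 neither.

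The X chromosome carried far more H3K27me3 in Asxl1-/-, with 205 peaks over 1.34 Mb in wild type and 1801 peaks over 15.6 Mb in Asxl1-/-. The covered length was 11.7 times that of wild type, against 1.02 on the autosomes. H3K4me2 and H3K4me3 on the X chromosome stood at 1.03 and 1.14. Of the X-linked genes in the lists, Gata1, the erythroid transcription factor, and Hcfc1, a partner of histone methyltransferases, gained H3K27me3, with 24.8 and 12.6 kb. Xist, the RNA that coats the inactive X chromosome, was looked up after the X chromosome had stood out. At its end near 103483233, H3K4me2 and H3K4me3 peaks of 7800 and 5400 bp were present in Asxl1-/- and absent in wild type.

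The Hox clusters, which code for position along the body axis, changed in different directions. Over the Hoxb cluster on chromosome 11, from 96194316 to 96368254, H3K4me3 covered 0.60 kb in wild type and 64.4 kb in Asxl1-/-, and H3K4me2 rose from 10.5 to 77.3 kb. H3K27me3 stayed over it, with 173.1 and 159.5 kb. Over Hoxc, H3K4me3 went from 50.3 to 89.5 kb. Over Hoxd it went the other way, from 21.8 to 4.40 kb. Over Hoxa, H3K4me3 held at 71.1 and 72.9 kb while H3K27me3 went from 44.5 to 7.88 kb, and Hoxa3, Hoxa6, Hoxa7, Hoxa9, Hoxa10 and Hoxa11 lost it, but 12.2% of windows of that length with enough H3K27me3 on chromosome 6 fell as much. At Hoxa10 and Hoxa11, Asxl1-/- still covered 69.9% of the wild-type H3K27me3 peak. Hoxb2, Hoxb4, Hoxb5, Hoxb6, Hoxb9, Hoxc4 and Hoxc8 gained H3K4me3. These were 7 of the 15 Hox genes without it in wild type, and 0 of 10000 random lists had as many, or 0.01% when matched on chromosome. Such lists draw separate genes, while Hox genes adjoin, and Hoxb5 and Hoxb6 share a peak. Of 10000 draws of runs of neighbouring genes as long as the clusters, 0.16% had as many gains. Neither the lists nor the runs were matched on H3K4me2 in wild type, which Hoxb5, Hoxb6 and Hoxb9 already had. Its part in the excess was not tested. Hoxd1 was the 1 Hox gene that lost it.

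**Figure D2:**
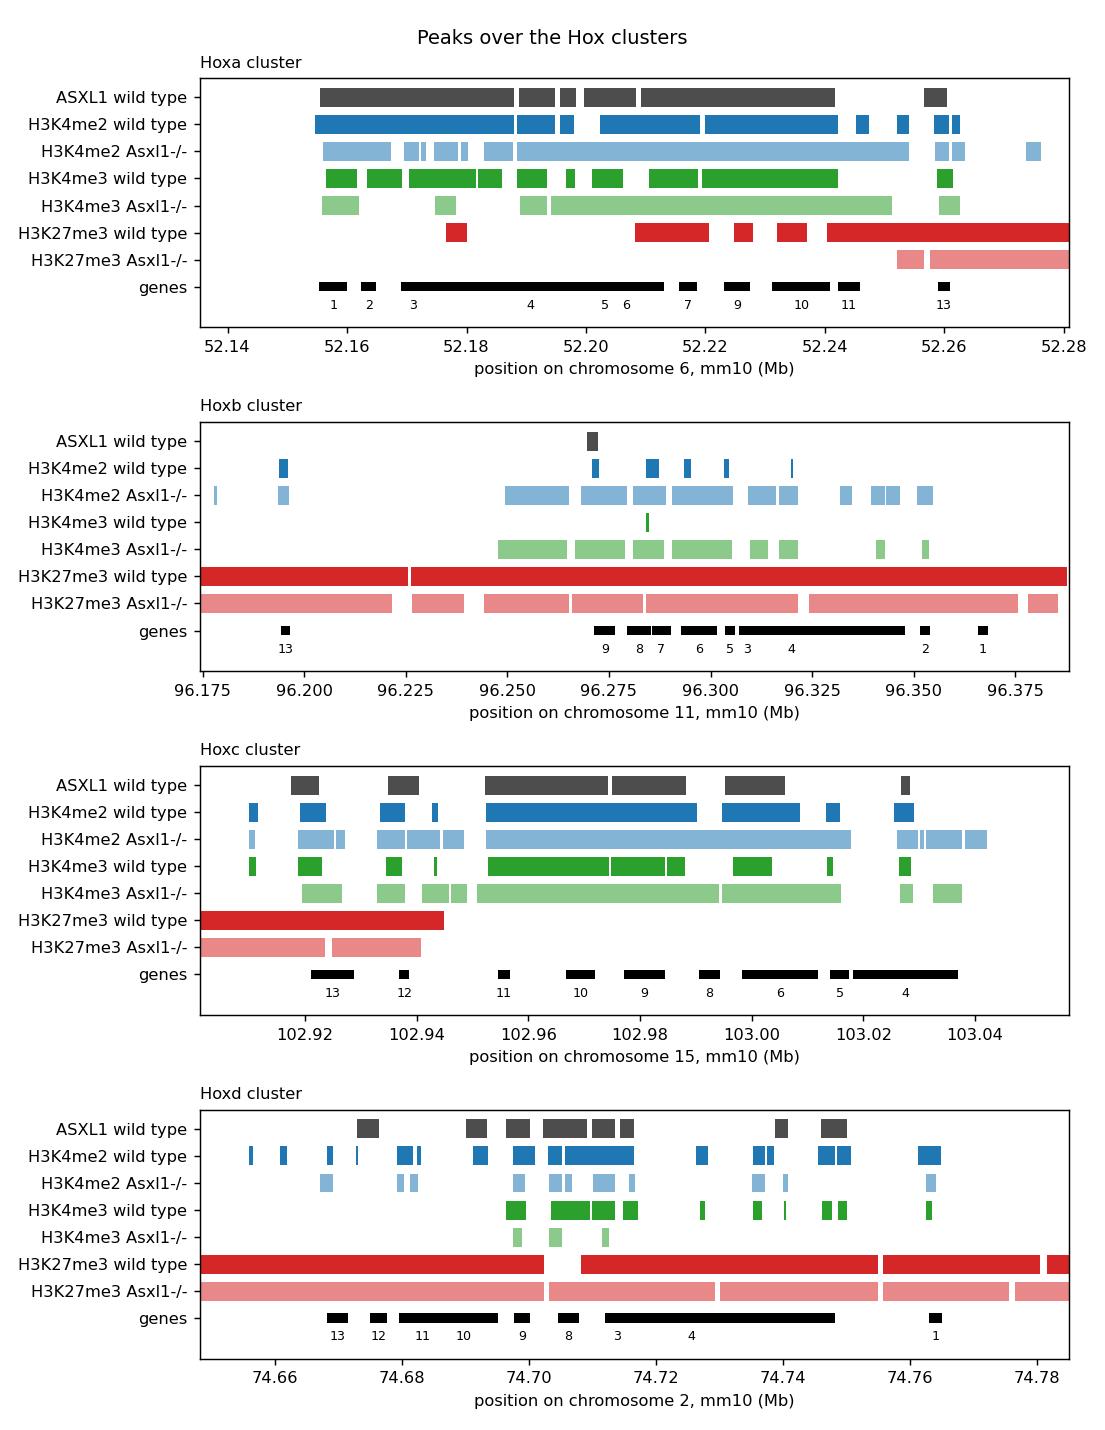
Peaks (bars) along the 4 Hox clusters in each library, with genes in black and numbered, against position in Mb. Green H3K4me3 bars cover 0.60 kb of Hoxb in wild type and 64.4 kb in Asxl1-/-, and red H3K27me3 bars over Hoxa fall from 44.5 to 7.88 kb.

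Osteoblast, stromal and adipocyte genes lost H3K4me3 at 0, 0 and 1 genes, against means of 0.74, 0.94 and 0.58 in random lists. All 14 osteoblast genes with H3K4me3 in wild type kept it, while Ibsp lost H3K27me3 (20.4 kb) and Bglap2 lost H3K4me2 (2.0 kb). Of the 13 adipocyte genes with H3K4me3, 12 kept it and Plin1, the lipid droplet coat gene, lost a peak of 0.800 kb. Cebpa and Lpl lost H3K27me3 (11.2 and 5.6 kb), and Cidec gained it. None of these adipocyte or osteoblast counts was reached in 5% or fewer of random lists. Chondrocyte genes lost H3K4me3 at Acan, Comp and Hapln1, 3 of 8, as many as in 0.81% of random lists, but with peak lists cut to equal length it was 1 of 5, as many as in 13.8%. Those wild-type peaks were 1.2, 4.4 and 0.800 kb wide. Ihh gained a peak of 4.4 kb. They lost H3K27me3 at Col11a2, Hapln1 and Matn3, against a mean of 2.18 in random lists. Stromal genes lost H3K27me3 at Alcam, Cspg4, Cxcl12, Grem1, Mcam and Nes, 6 of 8, as many as in 1.38% of random lists, with 6.4 kb lost at Cxcl12, and Thy1 gained it (3.8 kb). All 19 stromal genes with H3K4me3 kept it. Of the niche factors, 14 kept H3K4me3 and Lif gained it, in a peak of 8.8 kb of which wild type covered 5.4 kb, and Cxcl12 and Pdgfa lost H3K27me3, against a mean of 1.03 in random lists. Of the pluripotency genes, Sall4 lost H3K4me3 (2.4 kb), and Bmi1 and Klf2 lost H3K27me3, against a mean of 2.76. Over all lists, the 17 genes that lost H3K4me3 and 10 of the 13 that gained it had a peak that overlapped none of the other genotype, and the others were Cdkn1a, Hoxc8 and Lif. For H3K27me3 this held for 38 of 43 genes that lost it and 10 of 14 that gained it, and the gains in part were at Cdh5, Esam, Gata1 and Gli2. The losses in part were at Col11a2, En1, Hoxa10, Hoxa11 and Tie1. There Asxl1-/- still covered 27.6, 51.5, 69.9, 69.9 and 80% of the wild-type peak.

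Among signalling genes, 26 of 27 Wnt genes kept H3K4me3, and Wnt3 lost a peak of 1.0 kb. Dkk2, Fzd1, Fzd4, Sfrp2, Wnt2 and Wnt10b lost H3K27me3, against a mean of 5.63 such losses in random lists, and Wnt5b gained it (11.2 kb). TGF-beta and BMP genes kept H3K4me3 at 24 of 25, with a loss at Bmp7 (1.4 kb). Bmp6, Bmpr1b and Grem1 lost H3K27me3, against a mean of 2.06, and Id2 and Id3 gained it (10.6 and 1.8 kb), against 1.44. In the hedgehog and Notch list, Notch1, Notch3 and Notch4 lost H3K27me3, against a mean of 3.41, and Gli2 gained it (54.0 kb), against 0.416. All 34 chromatin regulator genes with H3K4me3 kept it. Asxl1, Hcfc1 and Cbx2, a Polycomb subunit, gained H3K27me3, against a mean of 2.21. At Asxl1 this was the gene end without H3K4me3. Kdm6b and Bmi1, another Polycomb subunit, lost H3K27me3, against 1.76. Cdkn1a, which codes for the cell cycle inhibitor p21, gained H3K4me3 (10.6 kb) and H3K4me2 (12.4 kb) and lost H3K27me3 (4.8 kb). Wild type also covered 4 kb of the gained H3K4me3 peak and 4.4 kb of the H3K4me2 peak. Cdkn1c gained H3K4me3 (2.0 kb), so that both list members without it in wild type gained it, as many as in 0.26% of random lists. All 27 marked ribosomal and housekeeping genes kept H3K4me3 and H3K4me2.

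Among lists of other cell types and lineages, haematopoietic genes kept H3K4me3 at 4 and gained it at Fcer1g (5.4 kb), and Ptprc, the pan-leukocyte gene, had no H3K4me3 in either genotype and lost H3K27me3. Endothelial genes lost H3K4me3 at Erg (2.4 kb) and H3K4me2 at Cldn5 and Tie1. They lost H3K27me3 at Cldn5, Tek and Tie1, against a mean of 2.72 in random lists, and gained it at Cdh5 and Esam (8.8 and 4.4 kb), as many as in 2.75% of random lists, but at 0 genes with a window of 2000 bp. Neural and developmental genes lost H3K4me3 at Gbx2, Nkx2-2, Nkx6-1 and Pax6, 4 of 14 (2.25% of random lists, but 11.2% with the window of 2000 bp). They gained H3K4me2 at Neurog1, Olig1 and Pax7 (1.26%) and lost it at Olig2 and Pax6 (18.7%). Neurod1 gained H3K4me3, and En1 lost H3K27me3, against a mean of 3.28. Epithelial genes lost H3K4me3 at Cdh1, Elf3 and Esrp1, 3 of 4 (0.49%), lost H3K27me3 at Cldn4 and Krt8, against a mean of 3.04, and gained it at Ttr. Muscle genes lost H3K4me3 at Ckm, lost H3K27me3 at Actc1 and Des (25 and 15.6 kb), against a mean of 1.48, and gained it at Cnn1. Des also gained H3K4me2. Of 106 combinations of list, mark and direction in which a member was able to change, 9 had as many changes as in 5% or fewer of random lists, and 10 did with matching on chromosome, where chance alone gives at most 5.3 on average. Of the 9, 4 did not stay at 5% or fewer in every alternative. These were chondrocyte and neural H3K4me3 loss, endothelial H3K27me3 gain and Hox H3K4me2 gain. The random lists were not matched on the other marks of a gene. Of 2618 genes with both marks at 1 end, 274 had H3K27me3 alone and 37 neither in Asxl1-/-. Of 9759 with H3K4me3 alone, the counts were 40 and 160. H3K27me3 was in wild type at 25 of 26 neural, 15 of 16 epithelial and 10 of 14 chondrocyte genes. Their H3K4me3 losses thus cannot be told apart from change common to genes with H3K27me3.

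**Figure D3:**
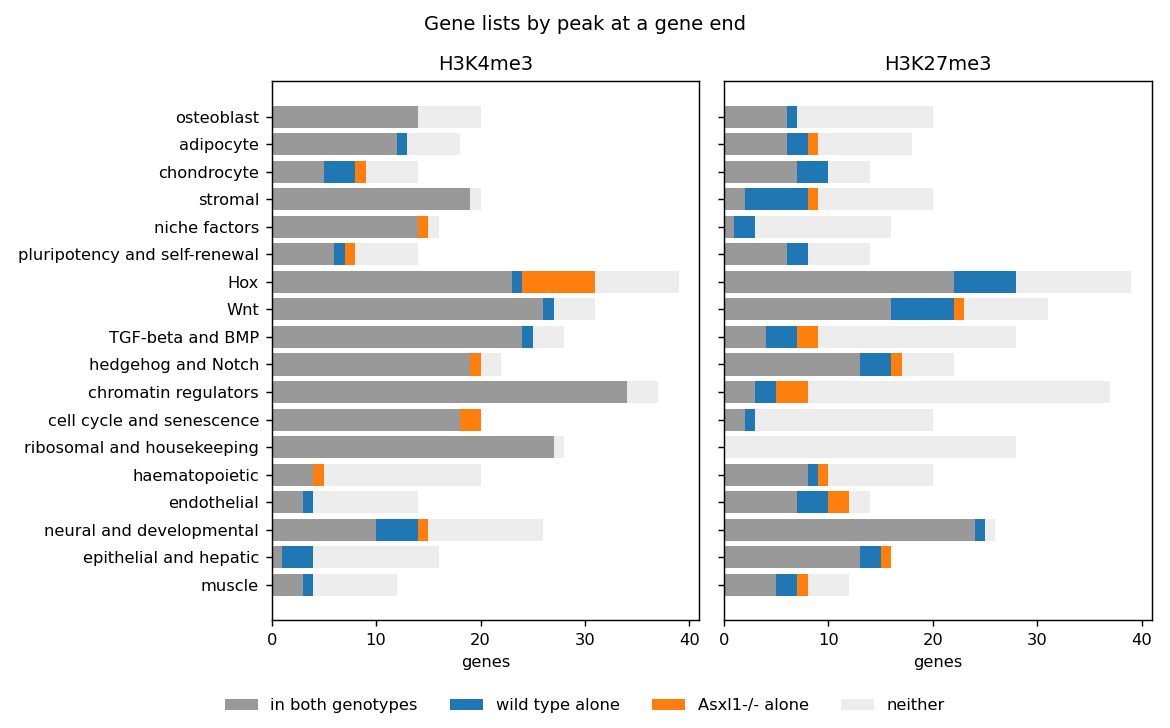
Number of genes (horizontal axis) of each list with a peak at a gene end in both genotypes, in wild type alone, in Asxl1-/- alone or in neither, for H3K4me3 (left) and H3K27me3 (right). Hox genes gained H3K4me3 at 7 genes, and stromal genes lost H3K27me3 at 6.

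ASXL1 peaks lay on H3K4 methylated chromatin. They come from 1 wild-type library, and without an ASXL1 library of Asxl1-/- cells it is unknown which of them depend on ASXL1. This limit also holds for the comparisons of genes with and without ASXL1. In wild type 95.3% (95 to 95.6) of them overlapped H3K4me2, against a mean of 12.6% for random regions, and 71.8% (71.1 to 72.5) overlapped H3K4me3, against 6.78%. Overlap with H3K27me3 was 9.06% (8.64 to 9.50), below the 12.0% of random regions. A gene end lay within 1000 bp of 53.5% of ASXL1 peaks, against 10.4% of random regions. ASXL1 was at an end of 92.1% (91.6 to 92.7) of the genes with H3K4me3 alone, 47.7% (45.8 to 49.7) of those with both marks at 1 end, and 3.41% (2.77 to 4.15) of those with H3K27me3 alone. All 28 ribosomal and housekeeping genes had it, as did 15 of 16 niche factors and 0 of 16 epithelial and hepatic genes. The widest peak, of 215.8 kb, covered ends of the apoptosis inhibitors Birc2 and Birc3, of Cfap300 and of Yap1, the coactivator of the Hippo pathway, on chromosome 9, in a region where H3K4me3 covered 101.2 kb in wild type and 40.2 kb in Asxl1-/-. Wide peaks also lay at Pgr (89.2 kb), Vgll3 (76.2 kb), the lamin gene Lmna with its neighbours Mex3a and Rab25 (73.2 kb), and Frmd8 (68.8 kb). At Lmna the widest H3K4me3 peak was 30.0 kb in wild type and 5.4 kb in Asxl1-/-, while the H3K4me2 peak was 32.8 and 31.0 kb, and chromosome 3 as a whole had an H3K4me3 ratio of 0.70.

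Genes with ASXL1 in wild type lost H3K4 methylation less often than other genes and gained it more often, and the reverse held for H3K27me3. H3K4me3 was lost at 1.45% (1.23 to 1.70) of genes with ASXL1 and 17.5% (15.9 to 19.1) of those without. Genes without ASXL1 but with H3K4me3 peaks of the same width classes lost it at 8.77%. H3K4me2 was lost at 1.06% (0.873 to 1.27) and 10.1% (9.0 to 11.2), with 7.67% for the matched genes. H3K27me3 was lost at 41.1% (38.7 to 43.5) and 19.2% (18 to 20.5), with 21.4% for the matched genes. Of genes without H3K4me3 in wild type, 22.6% (18.3 to 27.5) of 340 with ASXL1 and 4.77% (4.32 to 5.24) of the others gained it. For H3K4me2 these shares were 24.0% (16.7 to 32.6) of 121 and 8.01% (7.42 to 8.64), and for H3K27me3 4.23% (3.83 to 4.66) and 10.7% (9.94 to 11.4), none of them matched on width. For losses on autosomes, with matching on width and chromosome, the H3K4me3 shares were 2.28% with ASXL1 and 10.4% expected, over 5613 genes. For H3K27me3 they were 41.3% and 24.2%. The difference in loss from the matched genes was -7.32 percentage points for H3K4me3 and -4.26 with the window of 2000 bp. In the wider 50% of each list it went from -6.61 to -4.04 for H3K4me2 and from 19.7 to 10.9 for H3K27me3. In all, 153 genes with ASXL1 lost H3K4me3, and the 8 with the widest ASXL1 peaks were Synpo (48.0 kb), Krt80 (30.0 kb), Lyl1 (30.0 kb), Gipc1 (23.6 kb), Gpr146 (23.6 kb), Ecm1 (22.0 kb), Tbx6 (19.8 kb), a mesoderm regulator, and Septin9 (19 kb). At the end that lost H3K4me3, 7 of the 8 kept H3K4me2, and Synpo had it at its other end in Asxl1-/-. Lyl1, Gipc1, Ecm1 and Tbx6 have another gene end within 2000 bp. ASXL1 was counted at either gene end, so it need not lie at the end that lost H3K4me3. Width is all the lists give on the strength of a peak, so matching on it is partial. Whether a gene also held another of the 3 marks was not matched, and its part in these differences was not tested. For gains of H3K4me3 this includes H3K4me2, which 95.3% of ASXL1 peaks overlapped in wild type. Of the 484 genes that gained H3K4me3, 288 kept H3K4me2 and 13 lost it, and both groups held it in wild type. Another 149 gained both marks, and 34 had no H3K4me2. The higher share of H3K4me3 gains with ASXL1 thus cannot be told apart from H3K4me2 already there. Of the 2618 genes with both marks at 1 end, 274 had H3K27me3 alone and 37 had neither in Asxl1-/-. Of the 9759 with H3K4me3 alone, 40 had H3K27me3 alone and 160 had neither. Of the 2618, 719 had H3K4me3 alone, while of 2788 with H3K27me3 alone, 45 had H3K4me3 alone and 507 neither.

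**Figure D4:**
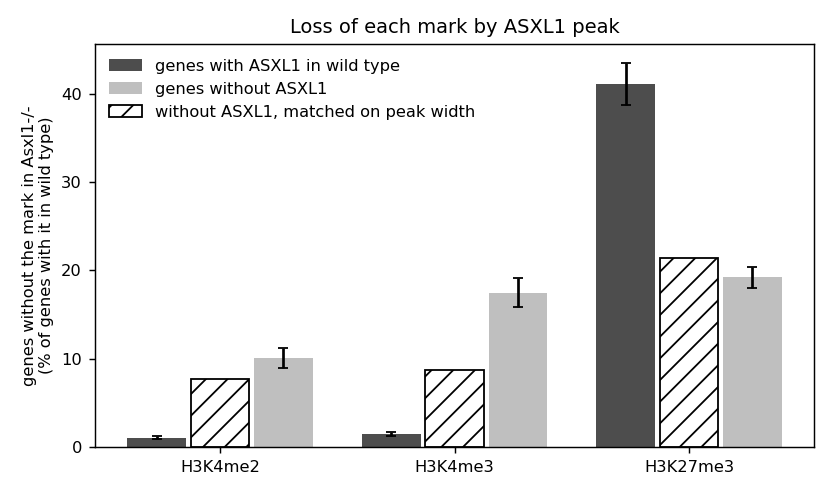
Percent of genes marked in wild type that had no peak in Asxl1-/- (vertical axis), for genes with and without ASXL1 and for genes without it matched on peak width. Error bars are 95% exact intervals for counting error. For H3K4me3 the values are 1.45, 17.5 and 8.77%, and for H3K27me3 41.1, 19.2 and 21.4%.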

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

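Of the tests in this part, all on chromosomes and on the X chromosome were chosen after the result was seen. The number of peaks moved in different directions between marks, and this difference was not tested: the ratio of Asxl1-/- over wild type was 0.932 for H3K4me2, 0.854 for H3K4me3 and 1.14 for H3K27me3. Outside the chromosomes compared, a few peaks were called on the Y chromosome, 2 in wild-type H3K4me2, 3 in Asxl1-/- H3K4me2 and 1 in Asxl1-/- H3K27me3. No library had a peak at an end of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d or Uty.

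The autosomes differed from each other in covered length. A difference in depth or enrichment between libraries would move all chromosomes alike, and the highest autosomal ratio of H3K4me2 was 2.53 times the lowest. Gene density of the chromosomes showed no clear relation to the ratio. The largest Spearman rho with genes per Mb was -0.17 (95% bootstrap interval -0.61 to 0.37, over 19 chromosomes, which are not samples). So wide an interval leaves a moderate relation open, and a part of gene density is not excluded. Different DNA copy number of chromosomes in the 2 cultures may be the source: the lowest Spearman rho between marks over the 19 autosomes was 0.933, and chromosome 4 was low only up to about 120 Mb, a point set by eye after seeing the data. No input library was analysed here, the 1 listed has no genotype in its labels, and an effect of the genotype on whole chromosomes stays open as untested.

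The gain of H3K27me3 on the X chromosome could come from an inactive X in the Asxl1-/- culture and none in the wild-type culture. The ratio of 11.7 on the X chromosome, with Xist marked by H3K4me2 and H3K4me3 in Asxl1-/- alone, goes with that. A deeper or better enriched Asxl1-/- H3K27me3 library is argued against by the autosomal ratio of 1.02. The labels do not give the sex of the animals. Wild type had no peak at an end of Xist, Ddx3y, Eif2s3y, Kdm5d or Uty, so its marks do not tell the sex either. With 1 culture per genotype, an effect of Asxl1 on the X chromosome stays open as untested.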

How the results depend on the processing

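Alternatives that rank or halve lists by width, or match on chromosome or on runs of neighbouring genes, were chosen after seeing the data. So were those that use whole genes, isolated gene ends, ends with H3K4me2 or selected chromosomes, except that autosomes only was planned for the shared peaks. The planned stricter lists by a statistic or a fold of at least 2, equal length by a statistic, 1 start per gene, and the whole read density ratio were not run, because the lists hold no such values. Unknown depth limits all comparisons. Counts of lost and gained genes stayed within 1.5 times in 41 of 62 cases. In the order H3K4me2, H3K4me3, H3K27me3, the shared share of wild-type and then Asxl1-/- peaks became 67.6, 78.2, 56.9 and 74.5, 86.3, 53.5% with 50% overlap, 71.0, 81.0, 63.4 and 76.5, 76.7, 58.4% in base pairs, 74.2, 74.9, 63.3 and 79.8, 85.8, 57.3% in the wider 50% of each list, and 75.1, 86.2, 60.4 and 76.0, 84.9, 61.9% at equal list length by width. On autosomes only, Asxl1-/- H3K27me3 moved to 64.6%. Over all annotated genes, where more genes enter, losses were 1373, 1088, 2872 and gains 1431, 876, 2852. More genes alone do not account for this, since the changed shares of marked genes rose too. For H3K4me2 the lost share went from 3.01 to 6.99%, and for H3K27me3 the gained share from 20.3 to 27.1%. On autosomes near the median ratio of another H3K4 mark, where fewer genes enter, losses were 272, 312, 885 and gains 335, 233, 362. Fewer genes alone do not account for the H3K27me3 gains, whose share of marked genes fell from 20.3 to 12.6%. The lost share was 25.5 and 26.1%. On these autosomes H3K4me2 covered 0.880 and H3K27me3 0.911 of the wild-type length, so this does not remove the shift of either. With no peak of the other genotype within 5000 bp, 250 genes lost H3K4me2 and 293 gained H3K4me3. In the wider 50% of each list, 1095 genes lost H3K4me2, 1694 lost H3K4me3 and 962 gained it. At equal list length, 324 lost and 872 gained H3K4me3. Among genes with no other gene end near, 306 gained H3K4me3, and at ends with H3K4me2 590 gained H3K27me3. Gained minus lost genes changed sign for H3K4me2 in the wider 50% (-145) and for H3K4me3 with the 500 bp window (8) and at equal list length (548), and for H3K4me2 (58) and H3K27me3 (-20) its interval spanned 0 over all annotated genes, so which change was more frequent is not settled for any mark. ASXL1 overlap was 84.7, 58.0, 6.12% with 50% overlap and 86.1, 55.9, 5.97% in the wider 50%. On the log2 scale its ratio to random was 1.18, 1.47, -2.48 among peak-holding regions, against 2.91, 3.41, -0.40 over the whole chromosome. The loss at genes with ASXL1 minus that at matched genes was -9.00 (H3K4me2) and -16.0 (H3K4me3) percentage points with no matching, -4.26 (H3K4me3) with the 2000 bp window, -4.04 (H3K4me2) and 10.9 (H3K27me3) in the wider 50%, and 17.0 (H3K27me3) with matching on width and chromosome. Its sign held in all alternatives run. For the lists, chondrocyte H3K4me3 loss rose to 13.8% of random lists at equal list length, and with the 2000 bp window endothelial H3K27me3 gain rose to 100% and neural H3K4me3 loss to 11.2%. With runs of neighbouring genes, Hox H3K4me2 gain rose to 12.2%. The cause of these shifts was not tested where none is named.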

Other observations

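Genes that mark position in the body also changed. They were listed before their values were looked at, apart from 2, En1 and Tbx5, which the gene lists of the report also hold and which did not change H3K4me3. Of 28 such transcription factor genes outside the Hox clusters, 7 changed H3K4me3, with 4 losses and 3 gains, among them Alx4, Hand2, Pax9, Pitx1 and Six2. Random lists matched on width and chromosome had a mean of 1.68 changes. The Hox tests by windows, and their bounds, were chosen after the cluster and window values were seen, and the list was drawn up after the Hox change was seen.

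A candidate explanation for the Hox pattern is cells from different positions along the body in the 2 cultures, and 0.07% of random lists had as many changed position genes. Those lists were not matched on H3K27me3. Of 2618 genes with H3K4me3 and H3K27me3 at 1 end, 274 had H3K27me3 alone and 37 neither in Asxl1-/-. Of 9759 with H3K4me3 alone the counts were 40 and 160. The share of 0.07% thus cannot tell body position from change common to genes with H3K27me3. The shift of the chromosome or ordinary variation along it was tested on windows of the cluster length that held enough of the mark to change as much. For H3K4me3 over Hoxb, 0% of 57 overlapping windows in 10 separate stretches rose as much. Their ratios of Asxl1-/- over wild type ended at 1.63, and chromosome 11 as a whole had 1.28, against 107 for Hoxb. This argues against a shift of the whole chromosome as the source over Hoxb. But those windows also held much H3K4me3 in wild type, where Hoxb held 0.60 kb. The test therefore cannot exclude ordinary variation at regions that start as low as Hoxb. Shift and variation are not settled for Hoxc and Hoxd, where 0.962% of 104 and 1.22% of 327 windows changed as much in H3K4me3. The fall of H3K27me3 over Hoxa could be such variation, since 12.2% of 907 windows fell as much. An effect of Asxl1 on these genes stays open as untested, since each genotype is 1 culture and the labels do not name the bones used.

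Chromosome 9 from 7 to 10 Mb, which holds Birc2, Birc3, Yap1 and Pgr, was covered more in wild type when summed. ASXL1 peaks covered 727.6 kb of it, H3K4me2 209.6 kb in wild type and 67.8 kb in Asxl1-/-, H3K4me3 101.2 and 40.2 kb, and H3K27me3 123.6 and 9.20 kb, while chromosome 9 as a whole was higher in Asxl1-/-. The excess lay from 7 to 9 Mb for H3K4me2 and H3K27me3, since from 9 to 10 Mb H3K4me2 covered 21.2 kb in wild type and 26.4 kb in Asxl1-/-, H3K27me3 0 and 4.8 kb, and H3K4me3 12.4 and 5.2 kb. A focal copy number difference, such as an extra copy of this region in the wild-type culture, is possible but not settled by a test chosen after the region was noticed: its best 1 Mb bin had rank 7 for the excess of wild type in H3K4me3 among 2470 autosomal bins, 2 of its 3 bins were among the top 100, and 1 among the top 10. If so, the widest ASXL1 peak and the narrower H3K4me3 peaks of Yap1 (12.4 and 6.4 kb) and Birc2 (14.2 and 4.6 kb) in Asxl1-/- may reflect DNA content.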
